A study of Mus musculus with 4 samples.

How the data were processed

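RNA was sequenced in 4 libraries of C3H10T1/2 mouse mesenchymal stem cells. Per the labels' protocols, total RNA was made into libraries with a stranded total RNA kit after removal of ribosomal RNA. Per the submitters' processing notes, reads were aligned with STAR 2.6.1d to mm10. The program that counted reads, its gene annotation and its strand setting are not given in the sources used here. The deposited values are the authors' whole-number counts per gene, not normalized, with 1 column per library and 54532 Ensembl gene identifiers. Of these, 54495 were found in GENCODE M21 (GRCm38/mm10), which gave symbols, biotypes, strands and coordinates. The 37 others held at most 0.00463% of a library's counts and were kept without a name.

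Because the kit keeps strand but the counting was not described, strand use was checked. Of 497 genes whose exons lie wholly under exons of genes on the other strand, 492 (99.0%) had 0 reads in all 4 libraries, against 20871 of 44468 genes of the same types (46.9%) without such overlap. Among the 195 whose partner held more than 1000 reads, 193 were at 0. Counting without strand that drops reads touching more than 1 gene would leave such genes at 0, so overlapping and antisense genes are uncertain here, and reads of the opposite strand outside annotated overlaps can be counted for a gene. Genes that share reads with near-identical copies are uncertain too.

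Groups came from the labels: WT (1 library), PRDX1MT (1 library, labelled both as an edit at a splice acceptor and as a Prdx1 knockout) and DKO (2 clones). The depth was 27570136 to 37685798 counts per library, and 3 counts, close to the one-sided 95% Poisson limit of a count of 0, were worth 0.0729 to 0.121 CPM per library. PCR reads without molecular identifiers are not independent molecules, so every interval and floor covers counting error only.

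Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The 3 groups were fitted together by edgeR's quasi-likelihood method (TMM scaling, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05 over 19446 genes). The fit had 1 residual degree of freedom, from the DKO clones, a prior degree of freedom of 6.54 and a common dispersion of 0.187, and it assumes that single libraries vary like the clones. DKO was tested against WT and against PRDX1MT. Single libraries were compared without a p, except for an edgeR contrast of PRDX1MT with WT tried as an alternative with the spread of the DKO clones. A gene passed a size rule if its TMM-scaled log2 CPM ratio (prior count 2) was at least 1 in size, the 2 libraries held at least 100 reads together, and the 95% conditional exact binomial interval of the ratio excluded 0. Levels of single libraries have exact Poisson intervals. Folds for DKO as a group are ratios of pooled reads over pooled effective library sizes. A fold against a group at 0 reads was taken against 3 counts over the group and is a lower bound.

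In all, 30 gene lists were fixed before the data were examined, as were the groups, tests, named-gene rule and most alternatives. They cover imprinted genes, germline genes silenced by methylation, pluripotency, Hox genes, clustered protocadherins, X inactivation, the DNA methylation machinery, histone-based silencing, the Prdx1 and Mmachc neighbourhood, cobalamin and one-carbon metabolism, peroxiredoxins and antioxidants, interferon response, immediate-early genes, p53 targets, unfolded protein response and ATF4, cholesterol synthesis, glycolysis and hypoxia, proliferation, replication histones, mitochondrially encoded genes, extracellular matrix, and smooth muscle, fat, bone, cartilage, muscle, endothelial, epithelial, neural and immune genes. Lists were tested in DKO by camera with a preset correlation of 0.01 and with an estimated one. The second test has only the fit's 1 residual degree of freedom, so it can hardly call a list. In PRDX1MT a list's median was placed among 10000 random lists matched on expression in 20 bins. Named genes were the 10 protein-coding genes with the largest rise and the 10 with the largest fall in log2 ratio among those that passed with at least 100 reads, up to 3 members per list with the smallest p (DKO) or largest ratio (PRDX1MT), and the genes of the Prdx1 neighbourhood with the Dnmt genes. Gm5886, Cytl1, Lpl, Hk2 and the genes named in the closing observations outside these were chosen after their values were seen. Cers4, 5730409E04Rik, Erg, Myl9, C1qtnf4 and Casd1 in DKO against PRDX1MT are genes that the rule names elsewhere.

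Alternatives were DESeq2 with its size factors, median-of-ratios or total-count scaling, no filter on low counts or 1 CPM in 2 libraries, small and mitochondrial RNA genes removed, only the groups compared, each clone left out, WT and PRDX1MT joined, a test against a 2-fold change, other read minimums (20 and 500), ratios and prior counts for the size rule, and, chosen after seeing the data, Gm26917 removed. The tests were checked on simulated counts for 19446 genes with 200 changed in each of 10 runs of 2 DKO against 1 WT. The changed genes were drawn from those with a mean of at least 100 reads per library, so recovery at lower counts is not known. Falls of 4-fold, 16-fold and 64-fold were recovered in 29.7%, 95.6% and 99.7% of cases and rises in 23.1%, 97.9% and 100%, with 18.2 false calls per run on average. In 20 runs without changed genes DKO against WT gave 2.35 calls on average and at most 10. That is more than an adjusted p under 0.05 should give, so the threshold let through more false calls than it names. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.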

Results

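Bulk RNA-seq counts were examined for 4 libraries of C3H10T1/2, a mouse mesenchymal stem cell line that can be turned towards bone, cartilage, fat and muscle. Per the series design text, the lines were made to study how Mmachc, a gene of cobalamin metabolism, is silenced when transcription of its neighbour Prdx1 runs on past the end of the gene. There was 1 library of unedited cells (WT), 1 of cells edited at the splice acceptor of intron 5 of Prdx1 (PRDX1MT), and 2 of clones in which Dnmt3a and Dnmt3b, the de novo DNA methyltransferases, had been targeted together (DKO, clones 1 and 5). The labels do not say whether the DKO clones also carry the Prdx1 edit, so what separates them from WT and PRDX1MT is not fully known. The deposited counts summed to 37685798 in WT, 27570136 in PRDX1MT, 34901511 in DKO clone 1 and 27789693 in DKO clone 5. Between 25191 and 26537 genes had at least 1 read in a library. Levels are given as CPM, counts scaled to a common library size with TMM factors. The DKO mean is over n = 2 clones with their SD, and WT and PRDX1MT had no replicates. Folds for DKO as a group are ratios of the pooled reads of both clones over their pooled library sizes. Ranges given for single libraries are 95% intervals of the counting and cover counting error only.

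Prdx1 reads were far lower in PRDX1MT, and reads of Ccdc163, the next gene on the same strand beyond Mmachc, were far higher. Prdx1 (ENSMUSG00000028691, GRCm38/mm10 chromosome 4, 116685544 to 116700822, plus strand), a peroxide-reducing enzyme, had 399 CPM in WT (393 to 405) and 31.2 CPM in PRDX1MT (29.0 to 33.4), which was 12.8-fold lower (11.9 to 13.8). Ccdc163 (ENSMUSG00000028689, 116708509 to 116751206, plus strand) had 5.91 CPM in WT and 44.8 CPM in PRDX1MT, 7.59-fold higher (6.60 to 8.76). Mmachc (ENSMUSG00000028690, 116702279 to 116708406, minus strand) lies between them, tail to tail with Prdx1 across 1457 bp and head to head with Ccdc163 across 103 bp. Mmachc reads were not lower in PRDX1MT. They stood at 11.1 CPM in WT (10.1 to 12.1) and 16.8 CPM in PRDX1MT (15.3 to 18.5), a log2 ratio of 0.60 that stayed under the size rule. Further along the plus strand, Tesk2, a kinase gene whose span overlaps that of Ccdc163, had 13.1 CPM in WT and 31.6 CPM in PRDX1MT (log2 ratio 1.26, 1.11 to 1.43). Hpdl, on the minus strand, had 1.24 and 3.78 CPM (3.05-fold higher, 2.15 to 4.38). Mutyh, Toe1, Akr1a1, Nasp, Urod and Hectd3 had log2 ratios between -0.84 (Urod) and 0.67 (Mutyh), under the size rule, and Zswim5 had 16 reads in WT and 0 in PRDX1MT. The counts behaved as though reads of both strands had been counted for a gene, so the share of Mmachc and Ccdc163 reads that came from the opposite strand is not known, and the 12.8-fold and 7.59-fold values compare 2 libraries with no replicate check.

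In the DKO clones none of the 3 genes passed the test against WT. Prdx1 had 362 ± 42.7 CPM (SD, n = 2; log2 ratio -0.14, SE 0.48), Mmachc 9.77 ± 5.29 CPM (log2 ratio -0.18, SE 0.63) and Ccdc163 5.35 ± 3.64 CPM (log2 ratio -0.15, SE 0.68), all at adjusted p = 1.0 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Mmachc was at 6.03 CPM in clone 1 and 13.5 CPM in clone 5, on both sides of the WT level. In clones 1 and 5 Prdx1 was at 392 and 332 CPM and Ccdc163 at 2.78 and 7.92 CPM. Neither clone thus showed the low Prdx1 and high Ccdc163 reads of the PRDX1MT library. This bears on whether they carry its edit, but with 1 edited library it does not settle it. Against PRDX1MT, Prdx1 in DKO had a log2 ratio of 3.54 (SE 0.59, adjusted p = 0.0987, edgeR with Benjamini-Hochberg adjustment), which did not pass.

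**Figure D1:**
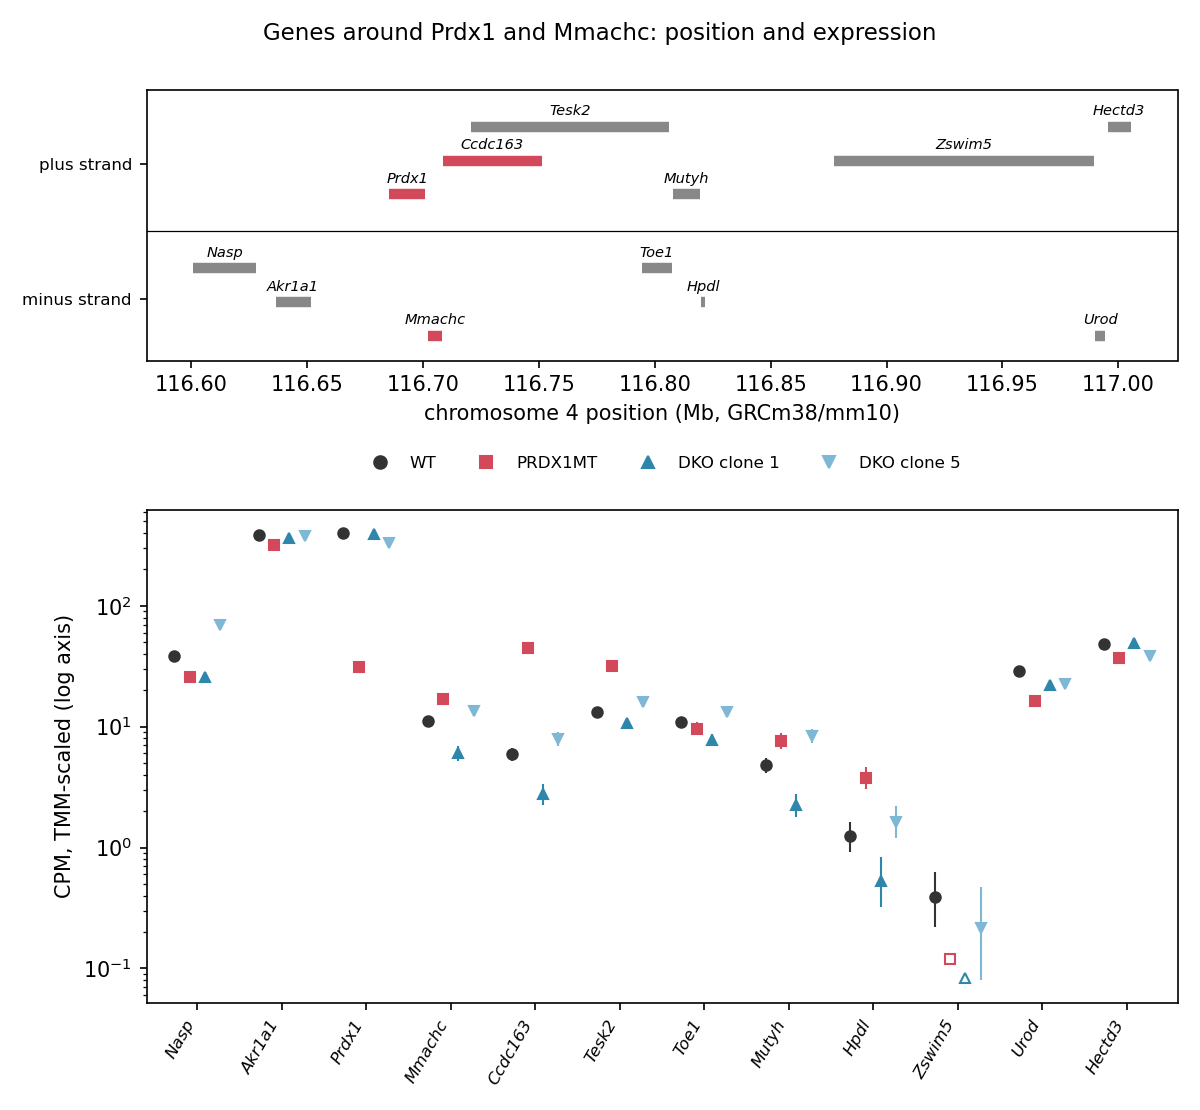
Upper panel: positions of Prdx1, Mmachc and their neighbours on chromosome 4 (Mb, GRCm38/mm10) by strand. Lower panel: TMM-scaled CPM of each gene on a log axis in the 4 libraries, with bars for 95% counting intervals and hollow markers, drawn at the CPM of 3 counts, for 0 reads; Prdx1 is lowest and Ccdc163 highest in PRDX1MT, at 31.2 and 44.8 CPM.

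Dnmt3a (chromosome 12, 3806007 to 3914443) had 43.7 CPM in WT, 80.9 CPM in PRDX1MT, 31.3 CPM in DKO clone 1 and 25.9 CPM in DKO clone 5. Its log2 ratio in DKO against WT was -0.61 (SE 0.44, adjusted p = 1.0, edgeR with Benjamini-Hochberg adjustment). Dnmt3b (chromosome 2, 153649450 to 153687730) had 3.28, 3.74, 2.83 and 2.03 CPM in the same order of libraries (log2 ratio -0.43, SE 0.68). A small edit can end a protein without changing its read count, so these values do not check the DKO label. Dnmt1, the maintenance methyltransferase, had 148 CPM in WT and 193 ± 115 CPM in DKO (SD, n = 2), and Uhrf1, its partner at replicating DNA, had 98.7 CPM in WT and 229 ± 196 CPM in DKO. Dnmt3l had 4 reads in DKO clone 1 and 0 in each of the other libraries.

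Among genes that passed the test between DKO and WT, most fell, many of them to no reads at all. Peg3 (chromosome 7, 6703892 to 6730431), an imprinted zinc-finger gene, went from 6876 reads in WT to 0 in both clones, at least 3520-fold lower taking 3 counts over both clones as the floor. Elastin (Eln, chromosome 5, 134702593 to 134747323), the protein of elastic fibres, rose from 35.5 CPM to 3140 ± 1603 CPM (SD, n = 2; log2 ratio 6.47, SE 0.96, adjusted p = 0.0441, edgeR with Benjamini-Hochberg adjustment). C1qtnf4 (chromosome 2, 90885860 to 90890525), which encodes a secreted protein of the C1q and TNF-related family, rose from 0 reads to 21.9 CPM in clone 1 and 11.4 CPM in clone 5, at least 238-fold (adjusted p = 0.0244, edgeR with Benjamini-Hochberg adjustment). Cdkn2a and Cdkn2b, neighbouring inhibitors of the cell cycle, fell to 0 reads in both clones, at least 222-fold and 247-fold.

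Across the 19446 genes tested, 91 changed at the adjusted threshold by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 3 higher and 88 lower. An unadjusted p under 0.05 by edgeR was found for 988. On simulated counts this threshold let through more false calls than it names. The third rise was Gm5886, a pseudogene (3.99 CPM in WT, 91.6 ± 28.4 CPM in DKO, adjusted p = 0.0321, edgeR with Benjamini-Hochberg adjustment), for which reads shared with a parent gene were not excluded. Of the 88 that fell, 83 were protein coding and 32 had 0 reads in both clones. Further large falls were at least 534-fold for 5730409E04Rik, 421-fold for Arhgef5, 397-fold for Sema3e (a semaphorin guidance cue), 369-fold for Cd24a, 362-fold for Cers4 (a ceramide synthase), 269-fold for Ccser1 and 232-fold for Ptprz1 (a receptor phosphatase), with edgeR adjusted p values (Benjamini-Hochberg) of 0.0171 to 0.0273. The ranking by fitted log2 ratio favours genes at 0 reads. Cytl1, which encodes a secreted cytokine-like protein and was chosen after its values were seen, went from 1478 reads in WT to 1 in clone 1 and 0 in clone 5, 2270-fold lower (407 to 89714; adjusted p = 0.0109, edgeR with Benjamini-Hochberg adjustment). The residual spread came from the 2 DKO clones alone, and the labels do not say how the clones were derived, so the p values measure only the spread between these samples. With WT and PRDX1MT joined, 21 genes were called without clone 1 (4 higher, 17 lower) and 92 without clone 5 (37 higher, 55 lower), and under a filter of 1 CPM in 2 libraries edgeR called 0, with 490 genes at an unadjusted p under 0.05. DESeq2 under the main filter called 262 (56 higher, 206 lower). The excess of lower genes was thus smaller by DESeq2. The fits without a clone took their spread from WT against PRDX1MT, which differ in genotype, so their counts are not comparable with the main ones. By the size rule against WT, 1088 genes were higher and 982 lower in clone 1, and 719 higher and 1084 lower in clone 5.

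**Figure D2:**
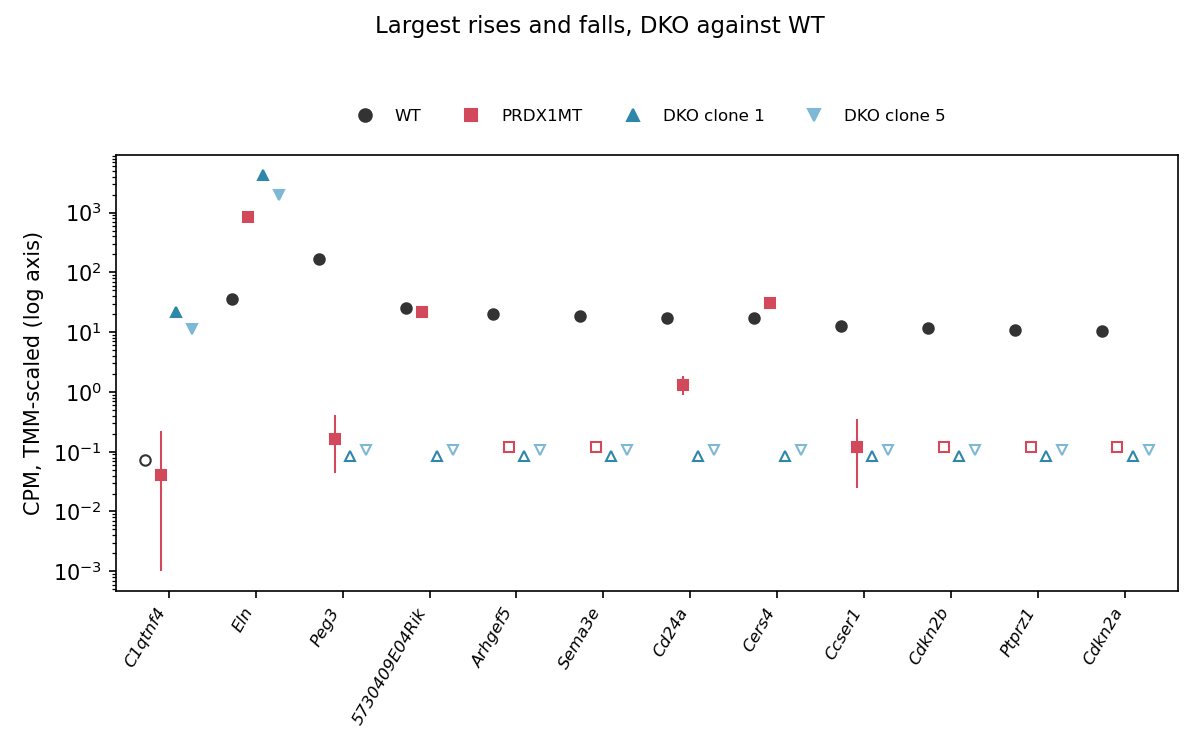
TMM-scaled CPM (log axis) of the 2 protein-coding genes that rose and the 10 with the lowest fitted log2 ratio among those that fell in DKO against WT, in each of the 4 libraries; bars are 95% counting intervals and hollow markers, drawn at the CPM of 3 counts, stand for 0 reads. All 10 genes that fell are at 0 reads in both DKO clones, and 5 of them (Arhgef5, Sema3e, Cdkn2b, Ptprz1 and Cdkn2a) also in PRDX1MT.

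Imprinted genes were lower as a list with the preset correlation only (median log2 ratio -0.58, camera adjusted p = 1.98e-20, and p = 0.0611 with an estimated correlation). The median was -0.35 in clone 1 and -0.91 in clone 5. Of 32 measured members 5 fell (Peg3, Meg3, Rian, Mest and Mirg) and 27 did not pass, with 10 lower when adjusted over the list alone. Meg3, Rian and Mirg lie together on chromosome 12, so the 5 are not independent. All 5 were also lower in PRDX1MT than in WT, 1039-fold, 12.8-fold, 47.1-fold, 176-fold and 35.8-fold in that order, although the labels name no Dnmt edit there. Meg3, a maternally expressed non-coding RNA, went from 4230 reads to 0, at least 2165-fold lower (adjusted p = 0.00875, edgeR with Benjamini-Hochberg adjustment). Mest, which is expressed from the paternal copy, fell 132-fold (log2 ratio -7.09, SE 0.57, adjusted p = 0.0107, edgeR with Benjamini-Hochberg adjustment), and Rian, with 3 reads in DKO, fell 1915-fold (655 to 9291). Chondrogenic genes were also lower as a list (15 members, median -0.36, camera adjusted p = 0.000869, and p = 0.152 with an estimated correlation). Their cartilage proteoglycan gene Acan fell 270-fold (105 to 995; adjusted p = 0.0321, edgeR with Benjamini-Hochberg adjustment), and 14 members did not pass, with 4 lower when adjusted over the list alone. The chondrogenic median was -0.37 in clone 1 and -1.98 in clone 5. Interferon-response genes had a median of -0.41 over 27 members (camera adjusted p = 0.00772, and p = 0.473 with an estimated correlation). Their median was -0.16 in clone 1 and -1.13 in clone 5. None of them passed singly, and 1 was lower when adjusted over the list alone.

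Extracellular matrix genes were higher as a list (40 members, median 0.75, camera adjusted p = 0.000869, and p = 0.137 with an estimated correlation), although only Eln rose. Tgfbi, a matrix protein induced by TGF-beta, fell (log2 ratio -6.52, SE 0.84, adjusted p = 0.0314, edgeR with Benjamini-Hochberg adjustment), and adjusted over the list alone 3 members were higher and 3 lower. The fibrillar collagen gene Col11a1 had 462 CPM in WT and 44.3 ± 17.5 CPM in DKO and missed the threshold (adjusted p = 0.0537, edgeR with Benjamini-Hochberg adjustment). Immediate-early genes (22 members, median 1.21, camera adjusted p = 0.000869, and p = 0.468 with an estimated correlation) had a median of 1.91 in clone 1 and -0.0090 in clone 5. Proliferation genes (34 members, median 0.48, camera adjusted p = 0.00772, and p = 0.644 with an estimated correlation) had a median of -0.34 in clone 1 and 1.02 in clone 5, so clone 5 alone carried that direction. Adipogenic genes had a median of 0.58 over 16 members (camera adjusted p = 0.0290, and p = 0.510 with an estimated correlation), with 0.95 in clone 1 and 0.07 in clone 5. In the immediate-early, proliferation and adipogenic lists 0 members passed singly by edgeR, over all genes or adjusted over the list alone. In all, 7 of 30 lists were called with the preset correlation and 0 with an estimated one. That second test had 1 residual degree of freedom, so it could hardly call a list and its 0 decides nothing either way.

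The other 23 lists did not pass, with camera adjusted p values from 0.0590 to 0.905. Single members fell in 3 of them. Perp (log2 ratio -6.15, SE 0.84, adjusted p = 0.0321) and Ddit4l (at least 90.6-fold, adjusted p = 0.0338) fell among 25 p53 targets, Vldlr (log2 ratio -4.05, SE 0.61, adjusted p = 0.0480) among 25 genes of the unfolded protein response and ATF4, and Erg (log2 ratio -5.60, SE 0.63, adjusted p = 0.0227), an ETS transcription factor, among 8 endothelial markers, all by edgeR with Benjamini-Hochberg adjustment. These lists had medians of 0.23, 0.27 and 0.71, with the same 2, 1 and 1 members lower when adjusted over the list alone. Of the list of germline genes known to be silenced by DNA methylation, 10 of 53 had enough reads to be tested, 0 rose, and their median was -0.52. Of the pluripotency list 2 of 20 genes were tested (median 1.04), and of the Hox genes 10 of 38 (median 0.07). Medians were -0.35 for cholesterol synthesis, 0.04 for glycolysis and hypoxia, 0.04 for cobalamin and one-carbon metabolism, 0.02 for peroxiredoxin and antioxidant genes, 0.17 for the DNA methylation machinery, -0.09 for histone-based silencing, -0.30 for X inactivation, 0.02 for clustered protocadherins and -0.14 for the Prdx1 and Mmachc neighbourhood. Among lineage and marker lists they were 0.47 for smooth muscle, 0.68 for muscle, -0.38 for bone, 0.71 for neural, 0.75 for immune and -0.82 for epithelial genes. They were 0.19 for replication histones and 0.07 for mitochondrially encoded genes. The mean had the opposite sign to the median for the bone (0.07), epithelial (0.22), endothelial (-0.07), Hox (-0.30), replication histone (-0.0061) and mitochondrial (-0.02) lists, and camera's direction went with the median for bone, epithelial and replication histone genes and with the mean for the rest. Adjusted over the list alone, 1 member was lower in each of the bone, smooth muscle and replication histone lists, where 0 passed over all genes by edgeR.

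Against PRDX1MT, the other single library, for which the labels name no Dnmt edit, most of the genes that passed the test in DKO were again lower. Cers4 (30.3 CPM in PRDX1MT and 0 reads in both clones) was at least 639-fold lower and 5730409E04Rik at least 457-fold (adjusted p = 0.0243 for both, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Erg was 42.6-fold lower (log2 ratio -5.44, SE 0.62, adjusted p = 0.0395, edgeR with Benjamini-Hochberg adjustment). Myl9, a myosin light chain of contractile cells, had 94.3 CPM in PRDX1MT and 8.48 ± 0.647 CPM in DKO (log2 ratio -3.47, SE 0.43, adjusted p = 0.0410, edgeR with Benjamini-Hochberg adjustment). The 2 higher genes were C1qtnf4, with 1 read in PRDX1MT, and Casd1, a sialic acid acetyltransferase gene with 0 reads in PRDX1MT. Casd1 was at least 66.1-fold higher in DKO than in PRDX1MT. It was not above WT there, with 13.6 CPM in WT and 8.13 and 7.77 CPM in clones 1 and 5.

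By edgeR 40 genes changed in that comparison, 2 higher and 38 lower, and 912 had an unadjusted p under 0.05. Of the 38, 33 had also fallen against WT, where independent lists of these sizes would share 0.172 genes. Simulated unchanged groups shared 0.25 on average and at most 2. Those runs made only 2.35 calls against WT and 2.7 against PRDX1MT on average, so they cannot gauge the 33. Part of the excess may come from the DKO libraries that both comparisons share. The mitochondrially encoded list was higher in DKO (median 1.44, camera adjusted p = 4.21e-07, and p = 0.279 with an estimated correlation), as were antioxidant genes (median 0.34, camera adjusted p = 0.00947, and p = 0.336 with an estimated correlation), a list that holds Prdx1, proliferation genes (median 0.54, camera adjusted p = 0.0109, and p = 0.648 with an estimated correlation) and Hox genes (median 0.64, camera adjusted p = 0.0453, and p = 0.224 with an estimated correlation). Cholesterol synthesis (median -0.62, camera adjusted p = 4.60e-06, and p = 0.426 with an estimated correlation) and imprinted genes (median -0.07, camera adjusted p = 0.00947, and p = 0.233 with an estimated correlation) were lower. For mitochondrially encoded genes the median to WT was 0.07 in DKO and -1.47 in PRDX1MT, and for antioxidant genes 0.02 and -0.37. These differences thus lay mostly on the side of the PRDX1MT library. For proliferation genes the clones stood on both sides of PRDX1MT, with medians to WT of -0.34 in clone 1, 1.02 in clone 5 and -0.05 in PRDX1MT. For imprinted genes clone 1 was above PRDX1MT and clone 5 close to it (-0.35, -0.91 and -0.89). The other 24 lists did not pass. With median-of-ratios scaling 13 genes were called, with only the groups compared 11, with WT joined to PRDX1MT 21 without clone 1 (4 higher, 17 lower) and 92 without clone 5 (37 higher, 55 lower), and under the filter of 1 CPM in 2 libraries 0 by edgeR, with 530 at an unadjusted p under 0.05. DESeq2 under the main filter called 215 (61 higher, 154 lower). By the size rule against PRDX1MT, 1015 genes were higher and 853 lower in clone 1, and 699 higher and 963 lower in clone 5.

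The PRDX1MT library differed from the WT library by more than the locus. Elastin had 35.5 CPM in WT and 850 CPM in PRDX1MT (log2 ratio 4.58, 4.50 to 4.66), and thrombospondin 1 (Thbs1), an adhesive matrix protein, 107 and 2194 CPM (log2 ratio 4.35, 4.31 to 4.40). Hey1, a target of Notch signalling, had 2.28 and 50.4 CPM (log2 ratio 4.43, 4.16 to 4.78), and Fras1, of basement membranes, had the largest rise in ratio (6 reads in WT and 207 in PRDX1MT; log2 ratio 5.34, 4.69 to 7.30). On the lower side, Penk, the proenkephalin gene, had 49.3 CPM in WT and 0 reads in PRDX1MT, at least 409-fold lower, and Peg3 had 4 reads, 1039-fold lower (406 to 3815). Arhgef5, Sema3e, Casd1, Stmn2, Cdkn2b, Ptprz1 and Cdkn2a also had 0 reads, at least 166-fold, 156-fold, 113-fold, 98.1-fold, 97.1-fold, 91.3-fold and 87.5-fold lower. Mest was 176-fold lower (126 to 254).

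By the size rule 1882 of the 12693 genes with enough reads passed, 921 higher and 961 lower. There is no replicate check on this comparison, which sets 1 library against another rather than the conditions, and between the DKO clones 2261 genes passed the same rule. With the spread of the DKO clones, edgeR called 0 genes between PRDX1MT and WT. Of the 88 genes that fell in DKO, 48 were lower, 7 higher and 33 within the rule in PRDX1MT, and independent lists would share 6.66 lower genes; both comparisons share the WT library, from which part of the excess may come. With median-of-ratios scaling 934 were higher and 945 lower, while scaled by total count 544 were higher and 1735 lower. The 2 libraries also differed in make-up. Gm26917, a non-coding RNA on chromosome 17, took 10.5% of the counts in WT and 22.3% in PRDX1MT (whether its reads are ribosomal RNA left after depletion was not checked here), and mitochondrially encoded genes took 2.08% and 0.519%.

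Gene lists stood apart from random lists of matched size and expression in 13 of 30 cases. The random genes were drawn without regard to shared regulation, so lists of genes that move together leave the range more readily. A percentile is thus a description and no test of a change. For scale, the immediate-early medians against WT were 1.91 in DKO clone 1 and -0.0090 in clone 5. Immediate-early genes had the highest percentile among the higher lists (median log2 ratio 1.25, percentile 100), with 15 of 21 members passing higher, among them Junb (log2 ratio 2.17), Dusp5 (1.95) and Atf3 (1.87). Smooth muscle contractile genes had a median of 0.70 (percentile 99.96), with Acta2, smooth muscle actin, at 687 CPM in WT and 2246 CPM in PRDX1MT (log2 ratio 1.71). Extracellular matrix (0.33, percentile 99.79), muscle (1.12, percentile 99.6), pluripotency (1.89 over 2 genes, percentile 99.37) and endothelial lists (0.71, percentile 97.74) were the others above the range. Acta1, the skeletal muscle actin, had 0.826 CPM in WT and 7.03 CPM in PRDX1MT.

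Below the range stood mitochondrially encoded genes (median -1.47, percentile 0), with mt-Rnr2 at -2.46 and mt-Nd2 at -2.04, and chondrogenic genes (median -1.17, percentile 0), where Cnmd (-7.07), Sox5 (-6.13) and Acan (142-fold lower, 48.3 to 690, from 3 reads) were lower. Imprinted genes had a median of -0.89 (percentile 0), with Rian at -5.51. Of 27 members with enough reads, 9 passed lower and 4 higher. Interferon-response genes had a median of -0.74 (percentile 0.02), with Gbp2 at -2.45. Peroxiredoxin and antioxidant genes had a median of -0.37 (percentile 0.03): besides Prdx1, Nqo1 (-1.60) and Gstm1 (-1.42) passed lower and 0 of 34 passed higher. Histone-based silencing (-0.41, percentile 0.06) and X inactivation genes (-0.48, percentile 0.93) were also below it. The other 17 lists lay inside, including cobalamin and one-carbon metabolism (-0.02, percentile 58.6), proliferation (-0.05, percentile 32.8) and bone genes (-0.50, percentile 2.86), where Spp1, osteopontin, was at 156 CPM in WT and 7.68 CPM in PRDX1MT (log2 ratio -4.33).

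**Figure D3:**
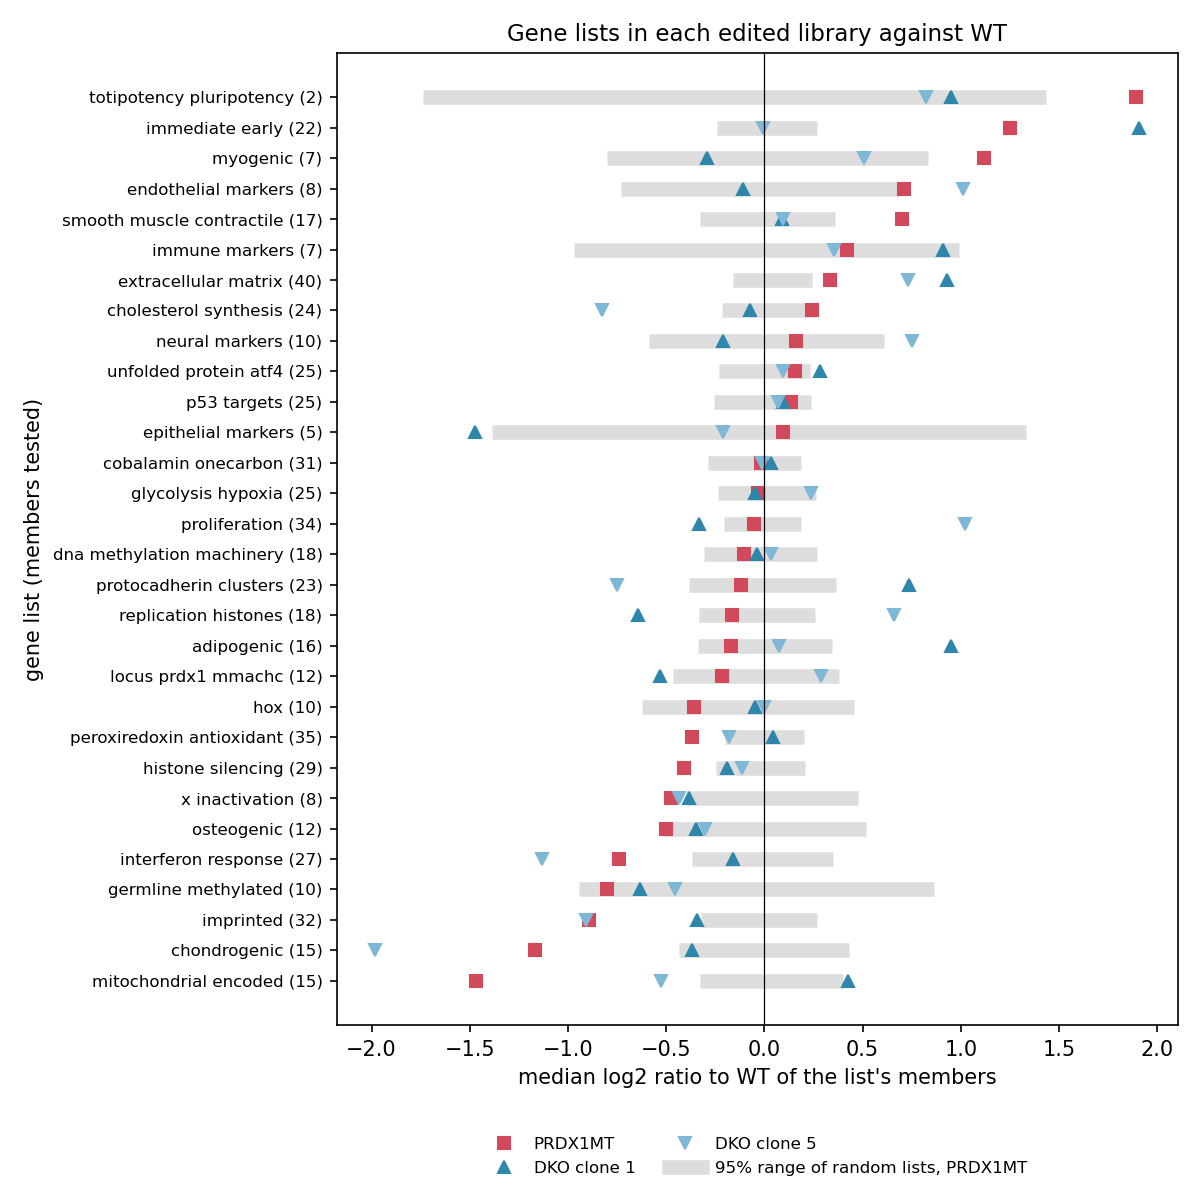
Median log2 ratio to WT of the members of each of the 30 gene lists in PRDX1MT and in DKO clones 1 and 5, with the number of members tested in brackets; grey bars are the 95% range of medians of 10000 random matched lists in PRDX1MT. Immediate-early genes lie at 1.91 in DKO clone 1 and at -0.0090 in clone 5, and mitochondrially encoded genes at -1.47 in PRDX1MT.

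The DKO clones differed from each other in as many genes as either did from WT, or more. Clone 5 was higher in 30 of 34 proliferation genes and 14 of 18 replication histones by the size rule, and clone 1 in 15 of 22 immediate-early and 12 of 23 protocadherin genes. Lpl, the lipoprotein lipase of fat cells, had 172 CPM in clone 1 and 0.726 CPM in clone 5, Uhrf1 had 90.5 and 368 CPM, and Hk2, a hexokinase, 296 and 44.5 CPM. By the size rule 2261 of 12317 genes differed between the clones (18.4%), 940 higher and 1321 lower in clone 5. Against WT the rule passed 2070 genes in clone 1 and 1803 in clone 5. The closest pair by Pearson correlation of log2 CPM across genes, which are not independent replicates, was nonetheless the pair of DKO clones (0.951), with 0.936 to 0.946 for the other pairs.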

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

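The alternatives were chosen before the data were examined, except the removal of Gm26917, which was chosen after. No paired analysis was possible because the labels name no pairs and WT and PRDX1MT had no replicates. Strand could not be varied, since each library has 1 column of counts. Where no reason is given, the cause was not tested. For DKO against WT (91 genes), median-of-ratios scaling (76), removal of small and mitochondrial RNA genes (90), only the groups compared (108), a test against a 2-fold change (75) and removal of Gm26917 (86) stayed within 1.5 times, while DESeq2 called 262 genes (56 higher, 206 lower), 90 of them shared, no filter 535 (130 higher, 405 lower) over 31043 genes tested, and WT joined with PRDX1MT 37 (2 higher, 35 lower), with 34 shared. A filter of 1 CPM in 2 libraries left 0 by edgeR (smallest adjusted p 0.149, 490 genes at an unadjusted p under 0.05). It removes genes present in WT alone, but 62 of the 91 were still tested, all 62 at an unadjusted p under 0.05 by edgeR. Removal alone therefore does not account for the 0. The prior degrees of freedom also differed, at 6.54 in the main fit, 4.38 under this filter and infinite without a filter. What they contributed was not tested. For DKO against PRDX1MT (40 genes), DESeq2 called 215 (61 higher, 154 lower), median-of-ratios scaling 13, no filter 404, only the groups compared 11, and the 1 CPM filter 0 by edgeR (530 at an unadjusted p under 0.05). Leaving out a clone with WT and PRDX1MT joined gave 21 genes without clone 1 (4 higher, 17 lower) and 92 without clone 5 (37 higher, 55 lower), from fewer samples and another control.

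The size rule passed 1882 genes in PRDX1MT against WT and 2261 between the clones. It passed 3616 and 3776 at 20 reads, 913 and 1444 at 500 reads, and 397 and 527 at a log2 ratio of 2, as looser and stricter rules must. Total-count scaling moved the PRDX1MT median over genes to -0.31 and the share of higher genes from 48.9% to 23.9%. It gave log2 ratios of -3.95 for Prdx1, 0.33 for Mmachc and 2.64 for Ccdc163. With the spread of the DKO clones, edgeR called 0 genes in PRDX1MT (801 at an unadjusted p under 0.05).

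With an estimated correlation 0 lists passed by camera (smallest p 0.0611), on 1 residual degree of freedom, where hardly any list could pass. With WT and PRDX1MT joined 7 passed, 4 of them shared, and mitochondrially encoded genes were then higher (median 0.52), as lower PRDX1MT levels entered the control. The proliferation median ran from -0.34 without clone 5 to 1.02, and the immediate-early median from -0.0090 without clone 1 to 1.91. Joined controls also turned the DKO log2 ratios of Prdx1 to 0.75, Tesk2 to -0.75, Mutyh to -0.23, Akr1a1 to 0.077, Toe1 to 0.039 and Hectd3 to 0.029, and total-count scaling that of Tesk2 to -0.10; none of these passed the test. Of 20 named genes called in DKO against WT, 11 were tested under the 1 CPM filter and lost their call there, as all genes did. Without that filter, 14 of the 20 were called in every alternative that tested them and kept both clones, where a gene left untested could not fail. Among values of all named DKO genes, called or not, 1083 kept their side of the threshold. They include uncalled genes that stayed uncalled, where a change of direction was not counted. A call was lost in 51 values, all of them of the 20 called genes, and gained in 32, in the same direction.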

Other observations

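The tests below, and the genes singled out, were chosen only after the results were seen. Some imprinted genes moved with their neighbours in the same chromosome region and others did not. On chromosome 7, Peg3 (6876 reads in WT) and its neighbour Zim1 (73 reads in WT) had 4 and 0 reads in PRDX1MT and 0 in both DKO clones. On chromosome 12 the maternally expressed Meg3, Rian and Mirg had 103, 90.9 and 10.1 CPM in WT and 8.04, 1.93 and 0.281 CPM in PRDX1MT. They had at most 4 reads each in a DKO clone. Dlk1, from the paternal copy, had 64, 16, 55 and 0 reads in WT, PRDX1MT and clones 1 and 5. Rtl1, also from the paternal copy, had 260, 10, 1 and 4. It lies on the minus strand between the plus-strand genes Meg3 and Rian. Reads of the opposite strand may therefore have been counted for Rtl1, and its own level is uncertain. On chromosome 6, Mest had 9875 reads in WT and 34, 82 and 33 reads in PRDX1MT and clones 1 and 5, whereas Copg2, which overlaps its end, had 68.0 CPM in WT and 45.0 to 68.4 CPM in the others. Peg10 had 57.2, 28.4, 0.224 and 4.25 CPM in the same order of libraries. Its adjacent gene Sgce had 33.1, 34.9, 2.55 and 12.9 CPM, and Casd1, further along, had 13.6 CPM in WT, 0 reads in PRDX1MT, and 8.13 and 7.77 CPM in the DKO clones.

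Cdkn2a had 434 reads and Cdkn2b 482 reads in WT, and both had 0 in all 3 edited libraries. Mtap, nearby on chromosome 4 (89137122 to 89181081), had 196 CPM in WT, 85.3 CPM in PRDX1MT (log2 ratio -1.20, past the size rule) and 150 ± 14.7 CPM in DKO (SD, n = 2). Counts do not tell a deleted gene from a silent one. Over all genes with enough reads, the median log2 ratio to WT on chromosome 6 was -0.28 in PRDX1MT, 0.22 in DKO clone 1 and 0.26 in DKO clone 5, and on the X chromosome it was -0.30, -0.17 and -0.20. Chromosome 4 had -0.18, -0.19 and 0.24 in the same order.

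More genes fell than rose in DKO against WT, 96.7% of the 91 (90.7% to 99.3%, exact binomial). Intervals of such shares take genes as independent, although some are neighbours, and leave out the spread between libraries. The excess was smaller by DESeq2 (56 higher, 206 lower), but not with WT and PRDX1MT joined and both clones kept (2 and 35). By size alone, among genes reaching 4 CPM, 98 genes were at least 16-fold lower and 3 at least 16-fold higher than WT in both clones, a share of losses of 97.0%. A loss needed 4 CPM in WT alone, and a gain needed it in both clones. That keeps the uneven layout of the test, so it cannot decide whether unequal power made the excess. Rules on single pairs ask the same of both libraries. The size rule gave 1088 higher and 982 lower in clone 1, and 719 and 1084 in clone 5. At 64-fold, losses exceeded gains in each clone, as given below. Under the 4 scalings tried, the lowest lower bound of the share of losses at 16-fold or more was 91.6%. The TMM factors ran only from 0.903 to 1.09, so no scaling tried could undo gaps of 16-fold. Scaling thus did not make losses of that size, but its part in smaller changes was not tested here. At 64-fold or more, PRDX1MT, in which the labels name no Dnmt edit, had 38 genes lost and 1 gained against WT (97.4%), clone 1 had 78 and 11 (87.6%) and clone 5 had 87 and 3 (96.7%), but from PRDX1MT to clones 1 and 5 losses exceeded gains again (48 to 27 and 57 to 7), as from clone 1 to clone 5 (12 to 2). Losses that accompany any edited clone, to an extent that differs by clone, and an effect of Dnmt3a and Dnmt3b therefore cannot be told apart without a matched unedited clone.

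The DKO clones shared many of their losses: of 10667 genes with at least 4 CPM in WT, 61 were lost, that is at least 64-fold lower, in both. The odds ratio of loss in clone 1 with loss in clone 5 was 1381 (726 to 2915), and PRDX1MT paired with clone 1 or clone 5 gave 291 (137 to 645) and 428 (196 to 1025). These intervals overlap between the DKO pair and PRDX1MT with clone 5, and all pairs share the WT library. Of the 61, 39 were not 64-fold lower in PRDX1MT, but 8 of these were at least 16-fold lower there, 11 were 2-fold to 16-fold lower and only 20 were less than 2-fold lower or higher. Whether losses in both DKO clones may follow from the Dnmt edits or from a common ancestor of the clones cannot be told apart, since the labels give no line of descent.

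Mmachc reads were not lower in PRDX1MT although the series was designed to study its silencing. A candidate explanation is readthrough from Prdx1, whose opposite-strand reads would be counted for Mmachc when strand is ignored. The density gained on Ccdc163 exons, 15.4 CPM per kb, would give 34.4 CPM over the Mmachc exons (32.0 to 36.8), more than the 5.79 CPM gained and more than the 16.8 CPM seen in all, so an even density misses the counts and readthrough stays open. No readthrough at all cannot be told apart from it either: the Ccdc163 ratio to WT had a lower bound of 6.60-fold, but from counting error alone, and with the spread of the DKO clones edgeR gave an unadjusted p = 0.00899 and a Benjamini-Hochberg adjusted p of 1.0. Higher output of the Ccdc163 promoter, and the level of Mmachc's own transcript, stay open too, as neither can be read from counts without strand.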
